A study of Lysinibacillus varians with 6 samples.

How the data were processed

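RNA was measured by Illumina sequencing in 6 libraries of Lysinibacillus varians strain GY32, a Gram-positive bacterium grown in Luria-Bertani broth at 30 °C. Per the labels, 3 libraries came from 5 h cultures of filamentous cells and 3 from 10 h cultures of rod-shaped cells, so cell form and culture time form a single contrast. Cultures were fixed with an RNA-stabilising reagent and RNA was purified on columns, per the labels' protocols. The protocols speak of triplicate pellets and do not say whether these came from separate cultures, so the p-values measure only the spread between these libraries.

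The submitters' processing notes name TopHat2 2.0.1 and SAMtools 0.1.18.0, and give no role or order for either. The counting program, the genome build, the annotation, the strand setting and any filter were not given in the sources used here. Without a strand setting, reads of overlapping or antisense genes cannot be told apart. The authors deposited 1 table per library. Per the file headers, each holds the count of uniquely mapped reads per gene, the gene length, the coverage as the percent of the gene length reached by reads, and RPKM (reads per kilobase of gene length, scaled to the library's total of counted reads). The deposited RPKM was recomputed from the deposited count, length and library total and differed by at most 4.73e-11. Uniquely mapped reads leave out reads that match several places, so genes with near-identical copies are undercounted. A gene with no read was not listed in that library's table and was entered as 0. Every gene length was a multiple of 3, so the lengths are coding lengths without untranslated regions.

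Genes are named in the files by locus tag only. The files do not pair the tags with gene names, products or coordinates, and no annotation was used here. For this reason none of the 28 gene lists fixed before the data were examined could be applied, and the list tests planned with camera were not run. The rule for named genes required a gene name, so no gene met it in full. The numerical part of the rule was kept: adjusted p under 0.05, a change of at least 2-fold, no overlap between the libraries of the 2 groups, a mean of at least 20 RPKM, and the largest fold changes first. It was limited, after the files were seen, to 2 genes that rose and 2 that fell, to which the gene with the most reads was added.

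Libraries held 14.8 to 18.4 M counted reads. The median listed gene had between 286 and 391 reads in a library. Replicate libraries of a group were compared by chi-square over genes with at least 10 reads in a pair. The statistic per degree of freedom was 27.2 to 215, so every pair differed by more than sampling noise, and all 6 libraries were kept as separate samples.

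The counts were tested in R 4.3.3 with edgeR 4.0.16: the default expression filter (minimum count 10, minimum total 15), TMM factors, quasi-likelihood fit and test of rod against filament, and Benjamini-Hochberg adjustment. The filter left 4287 of 4472 genes, and the 185 genes left out held 0.00578% of the reads. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. RPKM values of single genes and of runs are scaled to library totals, while log2 fold changes of the main test use TMM factors, so they differ in size. Changed genes had an adjusted p under 0.05, counted with and without a minimum of 2-fold. Abundance classes were set by the mean RPKM over all 6 libraries, with limits of 5, 20, 100 and 1000. Where the levels of single libraries were compared by class, rod replicate 3 alone set the classes with the same limits. RPKM was then scaled with TMM factors from genes of at least 100 RPKM. Tags that differ by 5, the step of the numbering, were treated as neighbours, and calls were permuted over the genes to test neighbouring genes. Comparisons of 1 value per library used a two-sided exact permutation test, for which 3 libraries against 3 cannot give a p under 0.1. The 10th percentile of RPKM was also compared in pairs by replicate number, with exact sign flips, which 3 pairs cannot take under a p of 0.25.

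The edgeR script was tested on simulated data, with counts drawn from the means of the 4287 genes and the 6 library sizes. The spread between libraries followed the trend with abundance fitted to these data, so single genes did not vary around that trend. Of 200 planted changes, it recovered 53.0% of the 2-fold and 89.0% of the 4-fold genes. False calls made up 4.70% of all calls. The planted rises and falls were equal in number, and all libraries otherwise shared the same gene proportions. The false-call share therefore does not cover differences in the level of low-abundance genes or in scaling.

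Replicate numbers in the labels are shared by both groups. The deviations of same-numbered libraries from their group means correlated across the 4287 genes at 0.47, 0.19 and 0.26 for numbers 1, 2 and 3. All lie over the limit of 0.1 set for pairing, so by this limit the numbers pair the libraries, which comes from this check and not from the labels. The main test had been fixed without the numbers and was kept, as were the tests of splits and single libraries, and the block was run as an alternative. In the 1222 genes of at least 100 RPKM the correlations were -0.20, 0.42 and -0.05. There only number 2 lay over the limit, so the pairing is not shown in abundant genes.

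Alternatives fixed before the data were examined were median-of-ratios factors, library totals without a factor, no filter, a filter of 50 reads in 3 libraries, DESeq2 1.42.0, limma 3.58.1 on log2 of the deposited RPKM plus 1, 0.1 or 5, leaving out each library, and the replicate block. limma kept genes with an RPKM of at least 1 in at least 3 libraries. Added after the data were seen were TMM factors from genes of at least 100 RPKM (also with the block), omission of both replicates numbered 1, genes of at least 20 RPKM only, and subtraction of each library's 10th percentile of RPKM. Planned removal of rRNA and tRNA rows was not run, because the tables name no such rows.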

Results

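Strain GY32 of Lysinibacillus varians was profiled at 2 stages of growth that the study took to represent its 2 cell forms, filaments at 5 h and rods at 10 h, in 3 libraries each. The filament libraries held 14.8 to 18.4 M reads and the rod libraries 15.5 to 17.3 M reads. Between 4275 and 4446 genes were listed per library, 4472 in at least 1 library and 4200 in all 6. Rank correlations of expression across genes were 0.967 to 0.988 between libraries of a group and 0.886 to 0.904 between groups. Genes are described by locus tag, length and position in the tag numbering, since the files do not pair tags with gene names.

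The comparison of rods with filaments addressed which genes differ between the 2 cell forms. Of 4287 tested genes, 1863 changed, 804 being higher and 1059 lower in rods (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was found for 1340 genes, of which 585 rose and 755 fell, and 1324 of these had no overlap between the libraries of the 2 groups. Across all tested genes 54.3% showed no overlap, where chance gives 10% for 3 libraries against 3. Changes of at least 8-fold were called for 36 genes that rose and 76 that fell, but this balance turned to 59 and 47 with library totals. limma gave 79 and 43, 49 and 37, or 37 and 31 with 0.1, 1 or 5 added to RPKM, subtraction of each library's 10th percentile gave 115 and 116, and without filament replicate 1 the 8-fold rises numbered 111. The balance of all rises and falls also turned. With library totals in place of TMM factors, 1017 genes rose and 722 fell, and limma on log2(RPKM + 1) gave 1199 and 744. The median log2 fold change of all tested genes was 0.13 with TMM and 0.47 with library totals. In the main test and under all 15 alternatives chosen in advance, 525 genes rose and 671 fell.

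**Figure D1:**
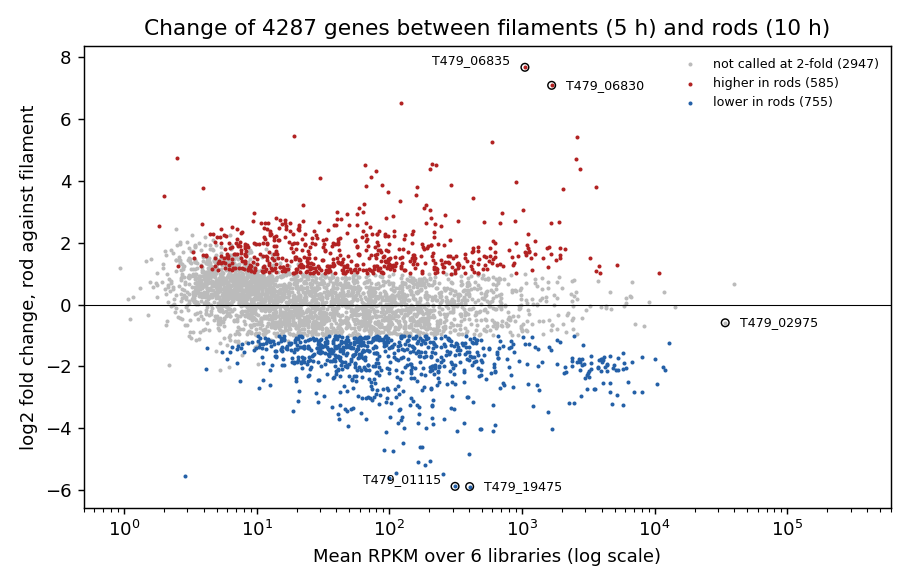
Log2 fold change of rods against filaments (vertical axis) against mean RPKM over the 6 libraries (horizontal log axis) for 4287 tested genes; each point is a gene, coloured where it changed at least 2-fold with an adjusted p under 0.05. The 585 rises extend into the low-abundance genes, while a group of falls lies at 1000 RPKM or more; circles mark the 5 genes given by tag.

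The 2 genes with the largest rises carry neighbouring tags. T479_06835, a gene of 1329 bases, stood at 8.21 ± 2.21 RPKM in filaments and at 2099 ± 412 RPKM in rods (SD, n = 3 each). Its log2 fold change was 7.68 with a standard error of 0.35, a 204-fold rise (edgeR adjusted p = 6.76e-09). T479_06830, of 1041 bases, went from 18.9 ± 4.71 to 3332 ± 604 RPKM, a log2 fold change of 7.09 with a standard error of 0.37 (edgeR adjusted p = 1.70e-08). In reads, T479_06835 had 143 to 204 per filament library and 36705 to 58771 per rod library. Both tags lie in a stretch of 3 consecutive genes that all rose, by a log2 fold change of 3.83 to 7.68.

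The largest falls were those of T479_19475 and T479_01115. T479_19475, of 2187 bases, went from 788 ± 260.1 RPKM in filaments to 18.7 ± 7.13 RPKM in rods, a log2 fold change of -5.88 with a standard error of 0.44 (edgeR adjusted p = 1.43e-07). T479_01115, of 1050 bases, went from 614 ± 334 to 13.2 ± 4.63 RPKM, also a log2 fold change of -5.88, with a standard error of 0.43 (edgeR adjusted p = 1.31e-07). Filament replicate 2 held T479_01115 at 228 RPKM, against 793 and 820.4 in the other filament libraries. T479_01115 lies in a stretch of 4 consecutive genes that fell with log2 fold changes of -5.88 to -4.60. The calls of T479_06835, T479_06830, T479_19475 and T479_01115 held under all 20 alternatives.

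T479_02975, of 3339 bases, took the most reads of any gene, 9.93% to 14.0% of a library. It stood at 35944 ± 6136 RPKM in filaments and 32180 ± 1527 RPKM in rods, values scaled to library totals. The difference did not pass the test with TMM factors (log2 fold change -0.59, standard error 0.36, edgeR adjusted p = 0.209). With library totals its log2 fold change was -0.16, and it did not pass either (edgeR adjusted p = 0.320). Without filament replicate 1 its log2 fold change was -0.87, and it passed (edgeR adjusted p = 0.00581, with a range of 0.00319 to 0.525 over the alternatives). Unique reads covered 74.6% to 79.8% of its length in the 6 libraries.

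**Figure D2:**
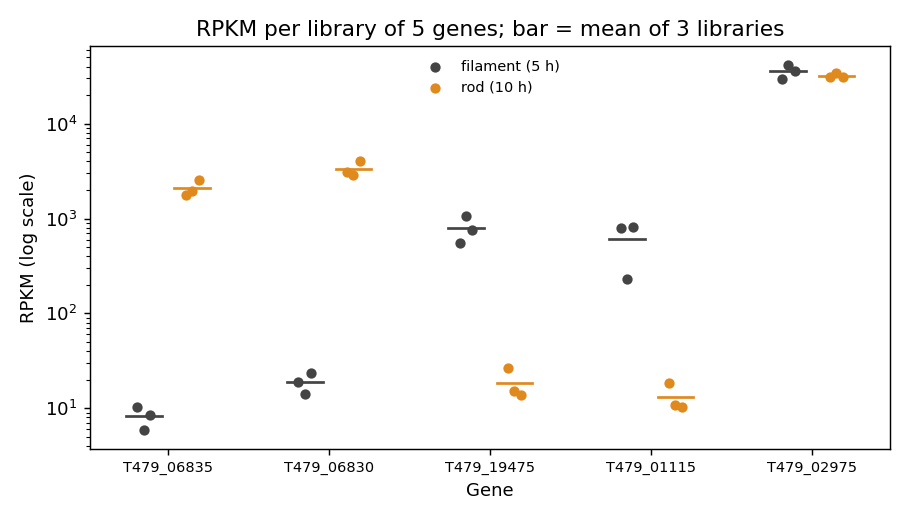
RPKM (vertical log axis) of 5 genes in each library, filaments in grey and rods in orange; points are libraries and bars are means of 3. T479_06835 and T479_06830 were higher and T479_19475 and T479_01115 lower in all 3 rod libraries than in any filament library, and T479_02975 overlapped between groups.

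The most abundant genes fell more often than they rose. Of 206 genes with a mean of at least 1000 RPKM, 97 fell, 46 rose and 63 did not pass the test, with a median log2 fold change of -0.61 (quartiles -1.92 and 0.59). The falls in this class numbered 87 to 116 over all alternatives, while the rises reached 80 with library totals and 83 with limma. The median stayed negative in each alternative, at -0.83 to -0.17. These genes took 64.4% ± 3.08 of the reads in filaments and 62.5% ± 0.68 in rods (SD, n = 3 each). The 10 genes with the highest mean share of reads took 24.3% ± 2.57 in filaments and 28.4% ± 0.23 in rods. Their share was higher in every rod library than in any filament library (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). The share of the first 100 such genes lay the other way, at 54.2% ± 3.20 and 52.4% ± 0.44, and T479_02975 alone took 9.93% to 14.0% in filaments and 10.4% to 11.3% in rods, each with a two-sided exact permutation p of 0.4.

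Genes of middle abundance had no stable direction as a group. In the class of 100 to 1000 RPKM, 238 of 1016 genes rose and 392 fell, and in the class of 20 to 100 RPKM, 307 of 1362 rose and 469 fell. Their median log2 fold changes were -0.22 and -0.19 with TMM factors, but 0.16 and 0.15 with library totals.

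Low-abundance genes rose more often than they fell in the main test, but not after every correction. In the class of 5 to 20 RPKM, 195 of 1328 genes rose and 98 fell, and under 5 RPKM 18 of 375 rose and 3 fell, with median log2 fold changes of 0.43 and 0.73. Over the alternatives these medians ran from 0.27 to 0.82 and from 0.38 to 1.36. Among called genes, the odds of a rise were 3.42 times higher under 20 RPKM than at 20 RPKM or more (Fisher's exact test across genes, which are not independent replicates, two-sided p = 4.55e-22, 95% interval across genes 2.62 to 4.47). The odds ratio depended on single libraries: it was 8.04 without filament replicate 1 and 1.77 without rod replicate 1. It was 5.32 with the replicate block and 6.11 to 7.44 with limma. The level of low-abundance genes also differed between libraries of the same group. The 10th percentile of RPKM was 4.75 in filament replicate 1, against 1.84 and 1.86 in replicates 2 and 3, and 7.64, 4.60 and 3.86 in rod replicates 1, 2 and 3. Ignoring the replicate numbers, the exact permutation test gave a two-sided p of 0.3. Paired by number, the rod library was higher in all 3 pairs, by 2.89, 2.76 and 1.99 RPKM (exact sign-flip permutation test, two-sided p = 0.25, the smallest that 3 pairs can give). Rises under 20 RPKM numbered 213 in all. They numbered 537 without filament replicate 1, 113 without rod replicate 1, 135 without rod replicate 3 and 390 with the replicate number as a block. Falls there numbered 101, and 60 and 64 without rod replicates 2 and 3, 26 with library totals, 29 to 30 with limma and 38 with TMM factors from genes of at least 100 RPKM. With each library's 10th percentile subtracted, 129 rose and 109 fell, and the direction turned without rod replicate 1 (73 and 100), 2 (79 and 85) or 3 (69 and 89). Rises still led without filament replicate 1 (273 and 109), 2 (116 and 111) or 3 (109 and 78).

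**Figure D3:**
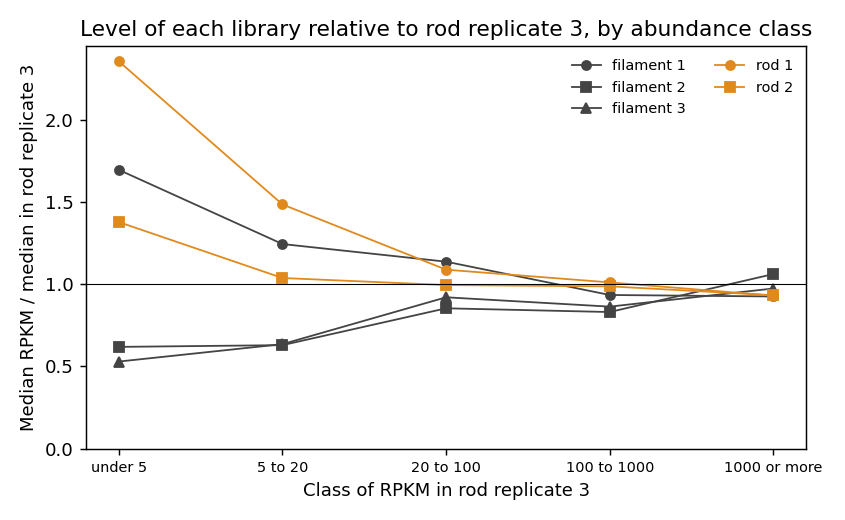
Median RPKM of each library relative to rod replicate 3 (vertical axis, from 0) in 5 abundance classes set by rod replicate 3 (horizontal axis), after scaling on genes of at least 100 RPKM; grey lines are filament and orange lines rod libraries. Under 5 RPKM the medians ran from 1.72 RPKM in filament replicate 3 to 7.65 RPKM in rod replicate 1. The lines converge in abundant genes, which this scaling centres by construction.

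Genes with neighbouring tags changed together. Among 3993 pairs of neighbouring tested genes, 663 pairs had both members changed at least 2-fold, 585 of them in the same direction and 78 in opposite directions. When the calls were shuffled over the genes, same-direction pairs averaged 198 and never exceeded 246 (permutation p = 0.0001, one-sided, the smallest that these shuffles can give). The log2 fold changes of neighbours correlated at 0.51 across genes, against at most 0.05 in shuffles. Unbroken runs of at least 5 neighbours that all changed at least 2-fold in one direction numbered 11 for rises, with 85 genes, and 22 for falls, with 167 genes. The number of runs shifted to 18 for rises and 11 for falls with library totals and to 24 and 11 with limma on log2(RPKM + 1). It rose to 30 and 30 without filament replicate 1. The replicate block gave 20 and 19, and with TMM factors from genes of at least 100 RPKM as well, 37 and 13.

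The longest runs were made of genes that fell. A run of 28 neighbouring genes, short ones with a mean coding length of 455 bases against 884 for all tested genes, fell by a median log2 value of -1.86, from a median of 5736 to 2073 RPKM. A second run of 13 genes of high abundance fell from a median of 6685 to 1498 RPKM (median log2 fold change -2.10). Another, of 21 genes at lower levels, fell from 194 to 26.5 RPKM, with a median log2 fold change of -3.08 and single genes between -2.73 and -3.54. The longest run of rises held 12 genes with a median of 509 RPKM in filaments and 1917 RPKM in rods (median log2 fold change 1.62). In 1000 shuffles of the calls no run was longer than 8 genes. With library totals all genes of these 4 runs were called in the same direction, but only 10 of the 13 in the run of 13 by at least 2-fold, and their median log2 fold changes were -1.49, -1.70, -2.73 and 1.96.

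**Figure D4:**
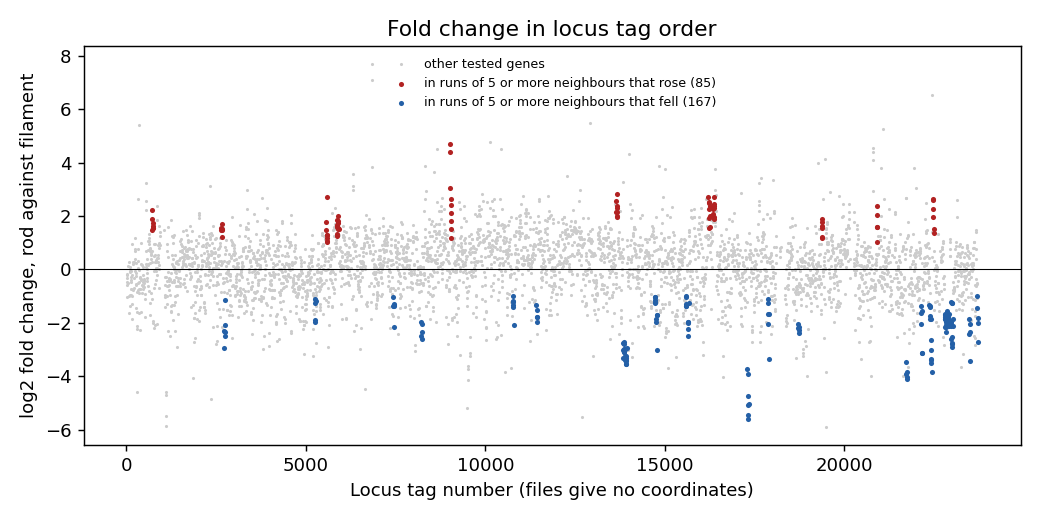
Log2 fold change of rods against filaments (vertical axis) in the order of locus tag numbers (horizontal axis) for the 4287 tested genes; coloured points are genes in runs of at least 5 neighbours that changed at least 2-fold in one direction, red for the 85 that rose and blue for the 167 that fell. The genes of a run stand as columns of coloured points, and the last of 20 equal stretches of tags held 78 falls and 8 rises of at least 2-fold.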

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

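The covered share of each gene's length, a column that no comparison of the report rests on, set T479_02975 apart from other abundant genes. Reads reached at most 79.8% of its length in any library and as little as 74.6%. The other 1008 genes with at least 1000 reads in every library each reached 95.4% or more in their best library. T479_02975 had at least 1489409 reads in every library, so low depth is no reason for the gap. No other explanation was tested. Groups of 3 libraries were not tested for single outlying libraries, and the study has a single contrast, so effects were not compared between contrasts.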

How the results depend on the processing

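The number of changed genes, 1863, stayed between 1513 and 2392 under the 15 planned and 5 added alternatives, and no gene called in the main test was called in the opposite direction under any of them. Filament replicate 1 had the strongest influence: leaving it out gave 2392 changed genes, and leaving out any other library 1513 to 1751. Rises moved from 804 to 1222 with limma on log2(RPKM + 5). Falls of at least 2-fold moved from 755 to 497 with library totals, and to 485, 491 and 448 with limma on log2(RPKM + 1), log2(RPKM + 0.1) and log2(RPKM + 5). These settings apply no composition factor, and library totals moved the median log2 fold change by 0.33. Of 1863 calls, 415 were not made with library totals. The replicate block gave 2109 changed genes, 1018 rises and 1091 falls. Within the 2-fold limit it gave 742 and 750, so it moved no total by more than 1.5 times, though it did so for rises under 20 RPKM and for runs of rises. TMM factors from abundant genes together with the block, added after seeing the data, gave 1393 rises, 1005 of them at least 2-fold. Those factors alone gave 973 rises and 810 falls, and omission of both replicates numbered 1 gave 910 and 1135. T479_02975 passed the test in 2 of 20 alternatives, at an adjusted p of 0.00581 without filament replicate 1 and 0.00319 without both replicates numbered 1, with a range up to 0.525. Same-direction neighbour pairs ranged from 438 to 816. The gene list tests and the removal of rRNA and tRNA rows were planned and not run. With the spread between libraries set by its trend with abundance, the simulation recovered 53% of 2-fold changes, so genes that did not pass are not shown to be unchanged. It planted 200 changes, far fewer than the 1863 called here, so its recovery may differ from that in the data.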

Other observations

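Of the tests in this part, the comparisons of split libraries were set before their results were seen, and the tests of background, scaling and tag position were written, and in part rewritten, after.

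Shorter runs of neighbouring genes held some of the largest falls. A run of 7 genes fell by a median log2 value of -5.05, from a median of 202 RPKM in filaments to 9.55 RPKM in rods. A run of 5 genes fell by -3.91, from 894 to 67.7 RPKM, and another of 7 genes by -3.37, from 111 to 21.4 RPKM. Among rises, a run of 8 genes went from 12.2 to 79.6 RPKM (median log2 fold change 2.23). Separate runs of 9 genes went from 4.86 to 30.9, from 3.62 to 17.1 and from 6.48 to 29.7 RPKM. Their median log2 fold changes were 2.28, 2.28 and 2.41. The median level of each run of 9 over all libraries was under 20 RPKM, where the number of rises depended on single libraries. When the tag numbers were divided into 20 equal stretches, the last held 78 genes that fell at least 2-fold and 8 that rose. The eighth held 54 rises and 19 falls. Its genes had a median level of 16.5 RPKM over all libraries, against 57.1 RPKM in the last stretch, so low-abundance genes weigh more in it. A single gene was listed in all 3 rod libraries and in no filament library, with 15 reads in total, and none the other way round. Tags that no library listed numbered 272 of 4744 steps.

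With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1863 changed genes, 1340 of at least 2-fold, and the highest of the other splits gave 0 for both, in edgeR at an adjusted p under 0.05. It was 1 of the 10 splits with a count as large, and the 3 others that part all same-numbered libraries also gave 0. At an unadjusted p under 0.05 the real split gave 2176 genes and the others 4 to 187. Every other split put filament and rod libraries into both groups, so the difference between the forms widened the spread within groups. Low counts there follow from this mixing, so they are no fair measure of what chance would give, and no conclusion is drawn from them.

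Filament replicate 1 stood apart from the other filament libraries in low-abundance genes, at 2.78 times their level under 5 RPKM. Its level in genes of 100 RPKM or more was 0.998 times theirs, but the scaling centres such genes by construction. For these levels RPKM was scaled with TMM factors from genes of at least 100 RPKM, and rod replicate 3 alone set the classes. The reads of filament replicate 1 numbered 1.01 times those of filament replicate 3, which argues against sequencing depth. In abundant genes called without it, its shift towards the rods was 6.98% of the gap between rods and filaments (2.72% and -2.54% for filament replicates 2 and 3). That small shift argues against a later stage of that culture as the whole cause. At 1000 RPKM or more its median was 1808 RPKM, against 2074 and 1903 in filament replicates 2 and 3. Rod replicates 1, 2 and 3 stood at 1818, 1822 and 1953. Filament replicate 1 thus lay nearer rod replicates 1 and 2 than filament replicates 2 and 3. Rod replicate 3 set the class, which favours high values in that library, so its own median is no fair comparison. No conclusion on the place of filament replicate 1 is drawn from this class. An even background, such as DNA left in the RNA, would add the same RPKM to every gene, and the added level was 3.23 RPKM under 5 RPKM, 5.08 at 5 to 20, 7.80 at 20 to 100, 1.57 at 100 to 1000 and -112 at 1000 or more. The level at 20 to 100 RPKM was 2.41 times that under 5 RPKM (95% interval over resampled genes 2.06 to 2.67). That goes against an even background, but the excess is that of a single library. Against the spread of filament replicates 2 and 3 the step between these classes came to 1.72 standard errors. The step was taken from differences per gene, but its standard error from class medians of only those libraries, so this value cannot decide. An even background, an uneven one and a difference in transcription stay open. Rod replicate 1 likewise had the highest 10th percentile of RPKM in its group, 7.64 against 4.60 and 3.86, so both replicates numbered 1 shared a high level. Why they shared it was not tested.

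Rises made up more of the calls among low-abundance genes than among abundant ones, with an odds ratio of 3.42 that was 8.04 without filament replicate 1 and 1.77 without rod replicate 1. With TMM factors from genes of at least 100 RPKM the odds ratio was 3.73. Without 1 library each, that value ran from 1.68 (without rod replicate 1) to 17.1 (without filament replicate 1). After each library's 10th percentile was subtracted the odds ratio was 1.43 (95% interval across genes 1.08 to 1.90), and without 1 library each it ran from 0.876 (without rod replicate 1) to 3.27 (without filament replicate 1). A higher even background in rods may therefore account for part or all of the excess among the calls, and the dependence on single libraries keeps this open. The median log2 fold change did not shrink alike. It went from 0.73 to 1.27 under 5 RPKM and from 0.43 to 0.37 at 5 to 20 RPKM. The subtraction also left 3884 tested genes in place of 4287, so the medians and odds ratios before and after it rest on different genes. A real difference between growth stages in weakly expressed genes stays open and was not tested.

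Falls outnumbered rises among genes of 20 RPKM or more, where rises made up 38.2% of the calls. They made up 51.6% with factors from genes of at least 100 RPKM, which centre those genes by construction. The main TMM factors were 1.18, 0.73 and 0.79 in filament replicates 1, 2 and 3. In rod replicates 1, 2 and 3 they were 1.23, 1.12 and 1.06. From highest to lowest they ranked the libraries as the 10th percentile of RPKM did. Factors from genes of at least 100 RPKM ran only from 0.93 to 1.04. The cause of the excess of falls was not tested, and the direction in this part rests on the scaling.

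If tag numbers follow the chromosome from the replication origin, faster replication at 5 h would lower the rod to filament ratio near both ends of the numbering. This hypothesis was tested by the rank correlation of log2 fold change with distance from the nearer end, against rotations of the tag order that keep neighbours together. The correlation was 0.19 over 4287 genes, and 0.152 of the rotations gave one as large in absolute value, so it did not pass. That share counts both signs, although the hypothesis predicts a positive correlation, and a one-sided share was not taken. The correlation was 0.21 under 20 RPKM and 0.10 at 20 RPKM or more, with two-sided rotation p of 0.0834 and 0.317. The order of the tags on the chromosome was not checked, which keeps this open.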
